A study of Mus musculus with 24 samples.

How the data were processed

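RNA of spinal cord microglia was measured by RNA-seq in 24 mouse libraries, 6 in each of 4 groups: female wildtype, female *Kdm6a* conditional knockout (cKO), male wildtype and male cKO. Groups were taken from the sample labels, and replicates were numbered 1 to 6 within each group in accession order, so the numbers pair no samples. Per the labels' protocols, RNA was purified with a Direct-zol RNA MiniPrep Plus kit and libraries were made with a KAPA Stranded RNA-Seq kit after mRNA enrichment. Per the submitters' processing notes, bcl2fastq 2.17, FastQC and Trimmomatic were used and the genome build was mm10. The aligner, the counting tool, its strand setting and the gene annotation behind the table are not given in the sources used here.

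The authors deposited 1 table of counts per gene for the whole series, with Ensembl gene identifiers and 1 column per library. The values were whole numbers with no normalization. Of 39017 identifiers, 37693 (96.6%) matched the GENCODE annotation of the same build, and the unmatched identifiers held 0.574% of the counts. Of all identifiers, 13754 had a total count of 0. Low counts were mostly even: 71.8% of counts from 1 to 10 were even, against 51.7% of counts from 1000 to 10000. If both mates of a read pair were counted separately, 1 fragment would give a count of 2 at many genes, and limits that rest on counting error would be too narrow. Because the counting is not described, reads of near-identical or overlapping genes cannot be assigned with certainty. This concerns *Lyz1* and *Lyz2*, the *H2-Q*, *Oas* and *Ifit* families, and the overlapping antisense pair *Xist* and *Tsix*.

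Total counts per library ranged from 27110133 to 40554736. Genes were tested where edgeR's filterByExpr kept them, which left 16535 genes. TMM factors ranged from 0.873 to 1.17. CPM values, each gene's deposited count scaled to the size of its library, were computed with these factors. No pair of replicates matched within sampling noise (chi-square of 15.3 to 395 per gene), so no library was merged with another. This does not show that each came from a separate animal.

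The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on all 4 groups in 1 fit, with 1 mean per group and Benjamini-Hochberg adjustment over the genes tested. Genes with an adjusted p under 0.05 were called. The comparisons were cKO against wildtype in females, in males, averaged over the sexes, the difference between the sexes in that effect, and female against male within each genotype. Fold changes are log2, cKO over wildtype or female over male, with standard errors (SE) from the same fit. Single quantities with 6 samples per group were compared with 2-sided exact permutation tests. In total 39 gene lists, for microglial states, immune and metabolic pathways and markers of other cells, were written before the data were examined, and 38 of them had enough tested members. They were tested with camera from limma 3.58.1 with a preset correlation between genes, again with an estimated correlation, and with fry. Members were counted by the adjustment over all genes and again with p adjusted over the list alone.

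The genes named were set by a rule written before the data were examined. It took *Kdm6a*, *Uty*, *Kdm6b*, *Tmem119*, *P2ry12*, *Apoe*, *Trem2*, *Spp1* and *Cd74* in every case. In each genotype comparison within a sex it took the 10 higher and 10 lower called genes with the smallest p, leaving out unnamed gene models and pseudogenes, and in the other comparisons 5 in each direction. Where fewer than 5 passed, it took all that passed plus those with the next smallest p, said not to pass. For each list with a call it took up to 4 members with the smallest p. Not every gene this rule names is reported here.

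Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE size factors, other low-count filters, fits of the compared groups alone, voom quality weights, surrogate variables from sva 3.50.0, a covariate for neuron, astrocyte and oligodendrocyte markers, the number in the sample titles as a random or fixed term, and each library left out in turn. Alternatives chosen after seeing the data were the removal of 4 doubted libraries (female wildtype 2, 3 and 5 and male cKO 3), counts divided by 2, thinning to the smallest total, a covariate for infiltrating cells, and a term for replicates 1 to 3 against 4 to 6 or a fit of either set alone. The procedure was tested on counts simulated from the means and sizes of these libraries, with 50 genes at each fold size. For the female comparison 64% of genes changed 2-fold and 90% of genes changed 3-fold were recovered, and for the male comparison 78% and 94%. False calls were 11 of 153 in the female and 11 of 159 in the male comparison. In each comparison 200 genes were changed, drawn from those with a mean of at least 1 CPM, so recovery at lower genes was not measured. The simulated libraries were independent, with no effect of title number, no difference between sets of replicates and no deviating library. Recovery and false calls in the real libraries may therefore differ. Figures were drawn with matplotlib 3.10.9.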

Results

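RNA of spinal cord microglia was sequenced from mice with experimental autoimmune encephalomyelitis (EAE), an immune-mediated disease of the central nervous system used as a model of multiple sclerosis. The gene of interest was *Kdm6a* (also called *Utx*), an X-linked gene for a histone demethylase that removes a repressive methyl mark and that escapes X inactivation, with *Uty* as its Y-linked relative. The design crossed genotype (wildtype or *Kdm6a* conditional knockout, cKO) with sex, with 6 libraries in each of the 4 groups. The design text names *Tmem119*-Cre, a driver for microglia, and RiboTag, an epitope tag on a ribosomal protein that allows ribosome-bound RNA to be pulled down from the Cre-expressing cells. All 24 libraries carried the treatment label EAE, so the disease itself was not compared with health. The labels do not say that each library came from a separate animal, and p-values measure the spread between these samples. Total counts ranged from 27110133 to 40554736 per library, and *Apoe* alone took 5.01% to 19.3% of them. Microglia lists, immune pathways, metabolic pathways and markers of other cells had been fixed before the data were examined.

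The first 2 principal components held 24.9% and 15.3% of the variance. Female wildtype replicate 5 stood at the far end of the first component. Replicates 4 to 6, numbered only in accession order, lay higher on average on both components (by 37.6 and 31.3; exact permutation p = 1.0e-04 and 2.5e-05, 12 libraries each), with overlap, and 7471 of 16535 genes differed between them and replicates 1 to 3 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). This grouping was chosen after seeing the data, and its p-values take no account of that choice. The labels name no batch, so comparisons are also given within each set of replicates. In 4 libraries other signals stood out. Female wildtype replicates 3 and 2 held 40 and 18 counts of the Y-linked *Ddx3y* and 7365 and 3904 counts of the hair follicle gene *Tchh*, male cKO replicate 3 held 16 counts of *Xist*, and female wildtype replicate 5 had a quality weight of 0.162. A weaker signal of *Tchh* stood in female cKO replicates 1 and 2 (474 and 588 counts, against 52 to 158 in the other female cKO libraries), and replicate 1 held 4 counts of *Kdm5d*; these were not among the 4. Counts without these 4 libraries, chosen after seeing the data, are given beside some of the counts with all 24.

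**Figure D1:**
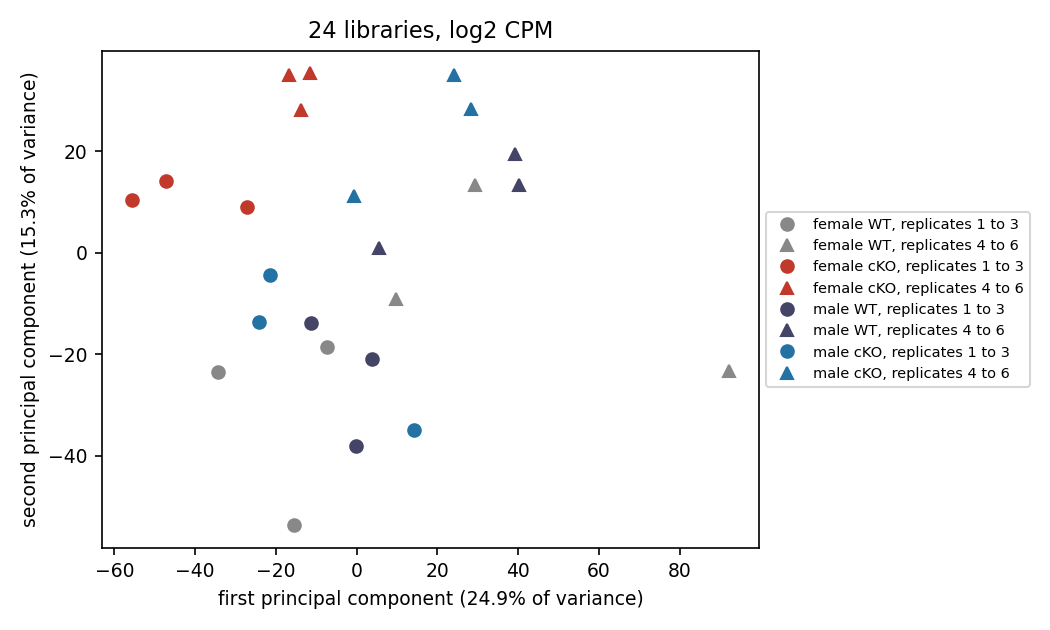
Principal components 1 and 2 of log2 CPM for the 24 libraries, 1 point per library, coloured by group, with circles for replicates 1 to 3 and triangles for replicates 4 to 6. The axes hold 24.9% and 15.3% of the variance, and female wildtype replicate 5 lies farthest out on component 1.

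*Kdm6a* (ENSMUSG00000037369, protein coding, chromosome X, 18162575 to 18279936 in mm10) was lower in cKO libraries of both sexes. Its level was 4.51 ± 1.37 CPM in female wildtype, 2.50 ± 0.671 in female cKO, 2.79 ± 0.705 in male wildtype and 1.08 ± 0.382 in male cKO (SD, n = 6 each). Female cKO libraries thus kept 55.4% of the female wildtype level and male cKO libraries 38.6% of the male wildtype level. The log2 change was -0.85 (SE 0.25, adjusted p = 0.031) in females and -1.36 (SE 0.26, adjusted p = 0.016) in males, and 2-sided exact permutation tests on CPM gave p = 0.0108 and p = 0.00216, the latter the smallest that 6 against 6 allow. Female cKO and male wildtype libraries differed by less than their spread (89.7% of the male wildtype level, exact permutation p = 0.496). The floxed exons are not given in the sources used here, and gene-level counts keep reads from the rest of the transcript. Within replicates 1 to 3 the change was -1.01 in females and -1.38 in males, and within replicates 4 to 6 -0.62 and -1.35, with none past the threshold at that size (adjusted p = 0.091, 0.16, 0.37 and 0.99). The female call was lost without female cKO replicate 2, 3, 5 or 6 or female wildtype replicate 2 or 3 (log2 change -0.79, -0.86, -0.84, -0.74, -0.78 and -0.74) and without the 4 doubted libraries (-0.81, adjusted p = 0.092), in a fit of the groups compared alone (adjusted p = 0.067), with title number as a random effect (adjusted p = 0.099) and with the infiltrating-cell covariate (adjusted p = 0.21). The male call was lost without male cKO replicate 2 or 6 or male wildtype replicate 2 (-1.31, -1.31 and -1.23), and with title number as a random effect (-1.46, SE 0.36, adjusted p = 0.33). *Uty* stood at 1.11 ± 0.693 CPM in male wildtype and 0.969 ± 0.564 in male cKO (SD, n = 6). The autosomal relative *Kdm6b* was 0.36 higher on the log2 scale in female cKO (SE 0.18, adjusted p = 0.29) and 0.25 higher in male cKO (SE 0.18, adjusted p = 1.0; 0.12 and 0.37 without male cKO replicate 6 or male wildtype replicate 6), neither past the threshold across all genes. Exact permutation tests on its CPM alone gave p = 0.013 in females and p = 0.288 in males (n = 6 each).

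**Figure D2:**
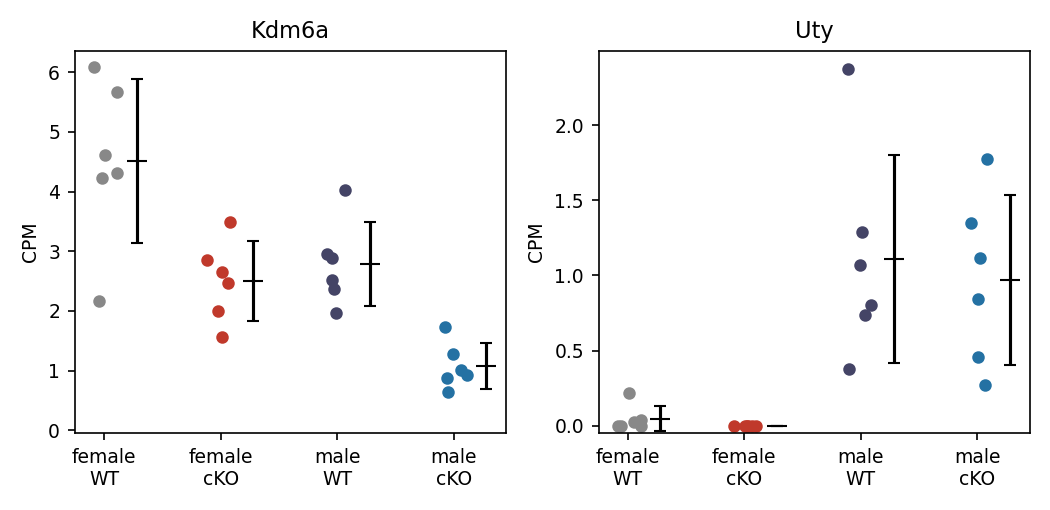
CPM of *Kdm6a* and *Uty* in each library (points) with the mean and SD of each group of 6. All 6 male cKO libraries lie below all 6 male wildtype libraries for *Kdm6a*.

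The first comparison asked what loss of *Kdm6a* changed in female microglia in EAE. *Il20rb*, a cytokine receptor subunit, rose from 1.35 to 20.8 CPM (log2 change 3.93, SE 0.27, adjusted p = 2.5e-10), and *Tgfb2*, a ligand of the TGF-beta family, rose by 3.45 (SE 0.29, adjusted p = 8.5e-09). *Tspan7*, a tetraspanin, fell from 338 to 89.5 CPM (-1.92, SE 0.10, adjusted p = 1.5e-12), and *Pld4*, an endolysosomal exonuclease, from 502 to 122 CPM (-2.04, SE 0.13, adjusted p = 1.4e-10), with 6 libraries per group. In all, 1279 of 16535 genes were called (7.74%), 549 higher and 730 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 3174 at an unadjusted p under 0.05, and 224 of the called genes were at least 2-fold higher and 415 at least 2-fold lower.

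Among the 10 higher genes with the smallest p were also the lysozyme gene *Lyz1* (log2 change 3.28), *Vopp1* (1.58), *Stac2* (2.32), the nucleotide exchange factor *Arhgef5* (1.75), the proteoglycan gene *Cspg4* (2.47), the mucosal addressin *Madcam1* (4.48, SE 0.47), the acid phosphatase *Acpp* (2.70) and the matrix protein periostin, *Postn* (2.94). Reads of *Lyz1* cannot be told with certainty from those of its near-identical neighbour *Lyz2*. The 10 lower genes also held the adaptor *Grap* (-1.88), *Tmem154* (-3.48), *Themis2* (-1.66), the receptor *Gpr35* (-3.76, from 56.1 to 4.14 CPM), the integrin subunit *Itgal* (-3.59), the lipase *Liph* (-1.70), *Alox5ap* (-3.43), whose product is needed for leukotriene synthesis, and *Ebi3* (-2.26), a subunit of heterodimeric cytokines. Each of these 10 higher and 10 lower genes, picked by p in the same libraries, separated all 6 cKO from all 6 wildtype libraries. Of the 1279 called genes 675 (52.8%) did so. Of all 16535 tested genes 737 (4.46%) did so, against 0.216% by chance. Without the 4 doubted libraries the number of genes changed by genotype in females was 869. Fits of replicates 1 to 3 and 4 to 6 alone called 458 and 658 genes, and with title number as a random effect, a number shared by several libraries of 1 genotype, limma called 803.

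Interferon-stimulated genes made the largest block of lower genes in female cKO. Of 40 tested members 31 fell (38 adjusted over the list alone) and the others did not pass, with a median log2 change of -1.05. *Oas3* (-3.24, SE 0.37) and *Oas2* (-3.03), sensors of double-stranded RNA whose family members share sequence, *Rtp4* (-1.56) and *Ms4a4c* (-1.35) led the list. Camera called the list lower (adjusted p = 3.1e-27; adjusted p = 0.19 with an estimated correlation), and fry found its members moving on balance downward (adjusted p = 0.001). The count of lower members was 21 without female wildtype replicate 5 and 17 without the 4 doubted libraries (median -0.90). It was 3 within replicates 1 to 3 (median -0.75), 29 within replicates 4 to 6 (median -1.40) and 20 with title number as a random effect. With surrogate variables 22 were lower and the median was -0.66. With the infiltrating-cell covariate, chosen after seeing the data, 4 were lower and the median was -0.67. Scores of monocyte-derived markers were lower in the same libraries as a mean over members (-0.36, exact permutation p = 0.00433, adjusted p = 0.030, n = 6 each), which was -0.49 as a median over members (adjusted p = 0.12) and -0.49 as a mean with an offset of 0.5 CPM (adjusted p = 0.015).

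Antigen presentation genes were lower too. Of 20 MHC class I genes 8 fell (14 adjusted over the list alone; median -0.46; camera adjusted p = 6.5e-07; adjusted p = 0.40 with an estimated correlation), among them *H2-T23* (-1.0), and the immunoproteasome and transporter genes *Psmb9* (-0.91) and *Tap1* (-0.95). Without female wildtype replicate 5 these 2 did not pass (-0.53 and -0.56, adjusted p = 0.054 and 0.090), nor did *Tap1* without female cKO replicate 1 or 3 (adjusted p = 0.052 and 0.051). The count was 4 and 1 without female wildtype replicate 4 or 5, and 2, 3, 2, 4, 4 and 5 without female cKO replicate 1, 2, 3, 4, 5 or 6, and 1 gene fell without the 4 doubted libraries. Of 15 MHC class II and costimulation genes 5 fell (7 adjusted over the list alone; median -0.51, and -0.23 without female wildtype replicate 5; camera adjusted p = 3.9e-05; adjusted p = 0.33 with an estimated correlation), with *H2-Ob* at -0.96 and the costimulatory ligand *Cd80* at -1.50, and 2 fell without the 4 doubted libraries. *Cd74*, the invariant chain, stood at -0.50 (-0.19 without female wildtype replicate 5) and did not pass (adjusted p = 0.30).

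Complement genes moved both ways. Of 17 members 5 fell and 2 rose (7 and 2 adjusted over the list alone; median -0.35, and -0.20 without female wildtype replicate 5; camera adjusted p = 0.023; adjusted p = 0.26 with an estimated correlation). *C4b* (-2.94) and *C2* (-1.17), components of the classical pathway, fell, and *Itgb2* (0.66), the shared subunit of the complement receptors, rose. Among 24 phagocytosis receptor genes 5 fell and 2 rose (6 and 4 adjusted over the list alone), including the Fc receptors *Fcgr4* (-3.28, and -2.55 without female wildtype replicate 5) and *Fcgr1* (-0.98) and the bridging ligand *Gas6* (-1.54). Of 20 chemokine genes 5 rose and 4 fell (6 and 7 adjusted over the list alone): *Ccl9* (1.45), *Ccl3* (1.52) and *Ccl6* (1.28) rose while *Ccl5* (-2.78) fell. In female wildtype replicate 5 *Ccl5* stood at 377 CPM, against 23.7 to 89.8 in the rest of its group, and without that library its change was -1.88 (adjusted p = 8.5e-04). Camera called neither of these 2 lists (adjusted p = 0.27 and 0.57; for chemokines its direction was upward while the median, -0.09, and the mean, -0.27, were negative), and fry's mixed test, for change in either direction, gave adjusted p = 4.1e-06 and 7.6e-09.

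Of 28 genes of disease-associated microglia, a state seen around damaged tissue, 8 rose and 1 fell (the same counts adjusted over the list alone; median 0.28; camera adjusted p = 3.9e-04; adjusted p = 0.47 with an estimated correlation). *Itgax* (1.49), the lipoprotein lipase *Lpl* (1.34), *Lyz2* (1.37) and *Ccl6* rose by over 1 on the log2 scale, while *Trem2* (0.25), *Spp1* (0.39) and *Apoe* (-0.45, and -0.14 without female wildtype replicate 4) did not pass. Without the 4 doubted libraries 5 rose and 1 fell. Homeostatic microglia genes split, with 5 of 28 lower and 2 higher (5 and 3 adjusted over the list alone; camera adjusted p = 0.23). At edgeR's unadjusted p under 0.05, 11 were higher and 5 lower. With 1 library left out the median log2 change of this list was 0.07 to 0.24. *Tmem119*, the gene whose promoter drives Cre here, fell by 0.77 (SE 0.15, adjusted p = 9.1e-04), as did *Fcrls* (-1.17) and *Crybb1* (-1.39, and -0.87 without female wildtype replicate 5), while *Siglech* (1.09) rose and *P2ry12* (0.89, adjusted p = 0.23) did not pass. *P2ry12* stood at 0.53 without female cKO replicate 1, and at 1.34 without female wildtype replicate 2, where it passed (adjusted p = 0.030). The number of higher homeostatic genes was 7 without female wildtype replicate 2 and 1 without female wildtype replicate 1, 3, 5 or 6 or female cKO replicate 1, 4, 5 or 6.

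Cholesterol synthesis genes rose, 7 of 21 (10 adjusted over the list alone; median 0.33; camera adjusted p = 6.5e-07; adjusted p = 0.19 with an estimated correlation). They included the regulator *Srebf2* (0.61, SE 0.13) and the demethylase *Cyp51* (0.69, SE 0.17). Without the 4 doubted libraries 8 of 22 rose. In TGF-beta signalling 4 of 23 genes rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.010; adjusted p = 0.33 with an estimated correlation), with *Ltbp3* (1.15) and *Smurf1* (0.75) higher and *Acvrl1* (-1.05) lower. Their median of 0.13 was 0.21, 0.20, 0.08 and 0.03 without female wildtype replicate 2, 3, 4 or 5 and 0.07 without female cKO replicate 1, and 1 gene fell without female wildtype replicate 1, 4, 5 or 6 or female cKO replicate 1, 2, 3, 4 or 5. The antioxidant and iron list gave 3 higher and 1 lower of 21 (3 and 1 adjusted over the list alone; camera adjusted p = 0.044; adjusted p = 0.42 with an estimated correlation). Its lower gene lost its call without female wildtype replicate 4, 5 or 6 or female cKO replicate 1, 2, 3, 5 or 6.

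Of 39 proliferation genes 9 fell, with a median of -1.50 (34 adjusted over the list alone; camera adjusted p = 2.7e-08; adjusted p = 0.59 with an estimated correlation). The count depended on single libraries. It was 17, 20 and 1 without female wildtype replicate 2, 4 or 5 and 3, 4 and 5 without female cKO replicate 1, 3 or 4. The median was -0.79 without female wildtype replicate 5 and -0.24 without the 4 doubted libraries. Oxidative phosphorylation genes (60 tested, median -0.23, camera adjusted p = 0.013; adjusted p = 0.78 with an estimated correlation) and ribosomal protein genes (66 tested, median -0.36, camera adjusted p = 2.4e-04; adjusted p = 0.68 with an estimated correlation) were called lower as lists, which rested in part on female wildtype replicate 5. Without it the medians were -0.01 and -0.15. EdgeR and DESeq2 called 0 of their single genes, with 3 and 15 lower at an unadjusted p under 0.05.

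Among markers of other cells, those of monocyte-derived cells were called lower (4 of 12 fell and 1 rose; 7 and 1 adjusted over the list alone; median -1.06; camera adjusted p = 0.0032; adjusted p = 0.26 with an estimated correlation). Mean marker scores differed for 2 of 14 cell types, monocyte-derived cells as given above and border macrophages (-0.21, exact permutation p = 0.00216, adjusted p = 0.030, n = 6 each). With the median over members in place of the mean the differences were -0.49 and -0.29 and neither passed (exact permutation adjusted p = 0.12 and 0.28). With an offset of 0.5 CPM both passed (-0.49 and -0.26, adjusted p = 0.015). Within replicates 1 to 3 and 4 to 6 the differences were -0.29 and -0.43 for monocyte-derived cells and -0.22 and -0.20 for border macrophages, where 3 against 3 cannot go below an exact permutation p of 0.1. The score of oligodendrocyte precursor markers, a list that includes *Cspg4*, was 0.32 higher (exact permutation adjusted p = 0.051, n = 6 each).

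The second comparison asked the same of males. Fewer genes passed, and most of these had passed in females. *Tspan7* fell from 344 to 182 CPM (log2 change -0.92, SE 0.10, adjusted p = 1.2e-05), *Tmem154* fell from 22.2 to 6.55 CPM (-1.76, SE 0.22, adjusted p = 1.8e-04) and *Itgal* by 1.37 (SE 0.24), while *Il20rb* rose from 1.17 to 3.65 CPM (1.64, SE 0.26, adjusted p = 0.0066), with 6 libraries per group. The chemokines *Ccl6* (1.05) and *Ccl9* (0.97), the adenylate kinase *Ak1* (1.01), *Arhgef5* (0.94), *Vopp1* (0.79, SE 0.14), *Smap2* (0.60), *Stac2* (1.13), *Klk8* (1.25) and *Vsig10* (0.71) rose. The glutamyl transferase *Ggt5* (-0.97), the matrix protein *Emilin2* (-1.27), *Liph* (-0.68), the urate transporter *Slc2a9* (-0.64), *Ppp1r12b* (-0.93) and *Prss46* (-2.30) fell, beside *Kdm6a* itself.

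EdgeR's quasi-likelihood test called 31 genes in males, 12 higher and 19 lower, of 803 with an unadjusted p under 0.05. These 803 are below the share of 0.05 of the 16535 tested genes that would pass where nothing changed. Of all 16535 tested genes 95 (0.575%) separated all 6 cKO from all 6 wildtype libraries, against 0.216% by chance. DESeq2 called 89, limma with quality weights 90, the fit without the 4 doubted libraries 48 and limma with title number as a random effect 2, *Tspan7* and *Tmem154*. Fits of replicates 1 to 3 and 4 to 6 alone called 0 and 0 genes by edgeR, with 1069 and 485 at an unadjusted p under 0.05. The count fell to 18, 19, 16 and 20 without male wildtype replicate 1, 3, 4 or 5 and to 16, 20 and 15 without male cKO replicate 2, 5 or 6. Calls of *Il20rb*, *Ak1*, *Ccl6*, *Ccl9*, *Vopp1*, *Arhgef5*, *Smap2*, *Stac2*, *Tspan7*, *Tmem154*, *Ggt5*, *Itgal* and *Emilin2* were kept whichever male library was left out.

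Among gene lists in males, cholesterol synthesis was higher (median 0.23; camera adjusted p = 1.7e-07; adjusted p = 0.13 with an estimated correlation) and interferon-stimulated genes lower (median -0.25, and -0.45 without male cKO replicate 1; camera adjusted p = 1.7e-10; adjusted p = 0.52 with an estimated correlation). EdgeR called 0 genes of either list. At an unadjusted p under 0.05 it found 5 higher cholesterol genes and 9 lower interferon genes, DESeq2 called 1 and 2, and 3 and 3 passed adjusted over the list alone. *Oas3* stood at -1.45 (adjusted p = 0.084). Homeostatic microglia genes were called higher as a list (median 0.18, and 0.12 without male cKO replicate 5; camera adjusted p = 0.0036; adjusted p = 0.67 with an estimated correlation). Lists for glycolysis (median 0.14, and 0.21 without male wildtype replicate 6) and the unfolded protein response (0.19) were also called higher by camera, and markers of endothelium (-0.49), fibroblasts (-0.62), monocyte-derived cells (-0.39) and Schwann cells (-0.90, and -0.40 without male wildtype replicate 1) lower. MHC class II and lysosome genes were called lower too, with medians that hung on single libraries. For MHC class II the median of -0.22 was 0.01 without male wildtype replicate 6 and -0.07 without male cKO replicate 4. For the lysosome -0.06 became -0.03 without male wildtype replicate 4 and -0.11 and -0.04 without male cKO replicate 4 or 5. None of these was called with an estimated correlation (adjusted p = 0.67 for MHC class II and 0.52 for fibroblasts) or by fry. Of 20 chemokine genes 3 rose (4 higher and 1 lower adjusted over the list alone), *Ccl6*, *Ccl9* and the receptor *Ccr1* (2.56), without a camera call (adjusted p = 0.27). *Tmem119* (0.01) did not pass in males.

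**Figure D3:**
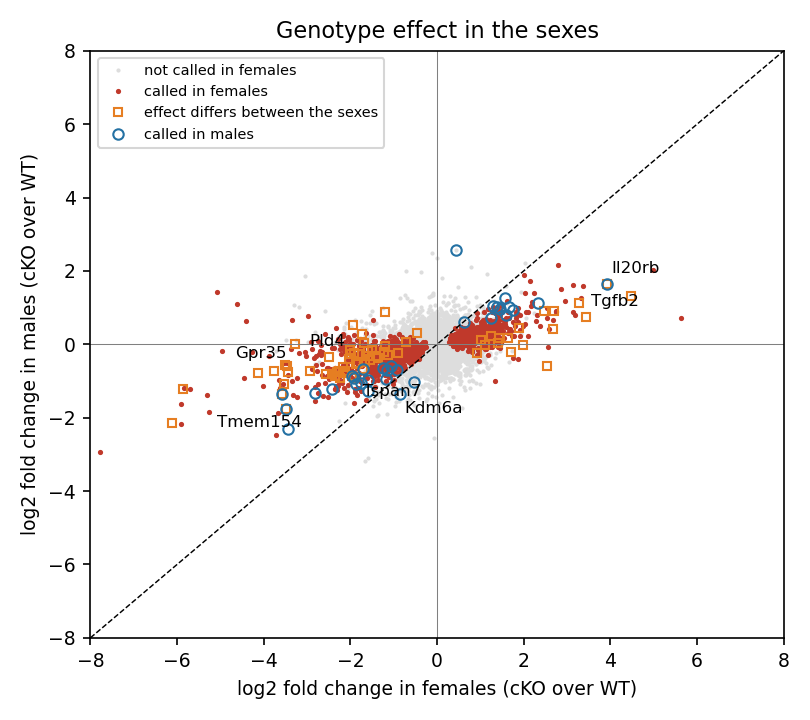
Log2 change of each tested gene in males against that in females, 1 point per gene, with called genes in colour, squares for an effect that differs between the sexes, and equality as a dashed line. Of the 31 genes called in males 29 were called in females, all in the same direction.

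Effects in the sexes shared direction. Of the 31 genes called in males 29 were called in females in the same direction. That is 11 higher and 18 lower, where independent lists of these sizes would share 0.398 and 0.839, though libraries of the sexes share title numbers and may not be independent. The 2 exceptions were *Ccr1* (2.56 in males, 0.43 in females) and *Gdf3* (-1.03 and -0.53), whose male calls were lost in 10 and 11 of the 12 fits with 1 library left out. Without the 4 doubted libraries *Gdf3* passed in females too (-0.91, adjusted p = 0.0085). Of the 1279 genes called in females 1145 (89.5%) had the same sign in males. Across all tested genes, which are not independent replicates, the log2 changes correlated with r = 0.416 and rho = 0.324. The r was 0.589 over genes of at least 10 CPM, 0.177 within replicates 1 to 3 and 0.400 within replicates 4 to 6.

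Tested directly, 68 genes had a genotype effect that differed between the sexes (18 with a more positive and 50 with a more negative effect in females), and all 68 were called in females with the larger size there. *Pld4* differed most clearly (difference in log2 change -1.65, SE 0.18, adjusted p = 3.2e-05; -2.04 in females and -0.40 in males), followed by *Gpr35* (-3.03), *Alox5ap* (-2.69), *Grap* (-1.36) and *Themis2* (-1.18). In the other direction stood *Tgfb2* (2.70, SE 0.40, adjusted p = 7.5e-04), *Il20rb* (2.29), the matrix protease *Mmp2* (1.11), *Lyz1* (2.14) and the adenosine receptor *Adora2a* (2.01). For *Kdm6a* the difference was 0.52 (SE 0.36, adjusted p = 0.87), with the larger loss in males. The genotype change of interferon-stimulated genes was more negative in females than in males (median difference -0.75; camera adjusted p = 4.2e-16; adjusted p = 0.49 with an estimated correlation), with 13 of 40 passing adjusted over the list alone. That of disease-associated microglia genes was more positive (median difference 0.26; camera adjusted p = 3.2e-04; adjusted p = 0.49 with an estimated correlation). Fry and fry's mixed test called 0 lists for this difference. Without the 4 doubted libraries 58 genes differed, DESeq2 called 150, and replicates 1 to 3 and 4 to 6 alone gave 15 and 4. Without male cKO replicate 1 or male wildtype replicate 1 the count was 45 or 43.

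Averaged over the sexes, 1082 genes changed, 457 higher and 625 lower. *Tspan7* (-1.42), *Tmem154* (-2.62), *Itgal* (-2.48), *Grap* (-1.20) and *Liph* (-1.19) led the lower genes, and *Il20rb* (2.78), *Vopp1* (1.19), *Stac2* (1.73), *Lyz1* (2.21) and *Arhgef5* (1.34) the higher. Of the interferon list 21 of 40 fell (37 adjusted over the list alone; camera adjusted p = 1.1e-26; adjusted p = 0.14 with an estimated correlation), and of the cholesterol list 7 of 21 rose (11 adjusted over the list alone; camera adjusted p = 9.0e-09; adjusted p = 0.067 with an estimated correlation). The number of genes changed by genotype averaged over the sexes was 463 and 546 in replicates 1 to 3 and 4 to 6 alone, and 330 by limma with title number as a random effect.

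**Figure D4:**
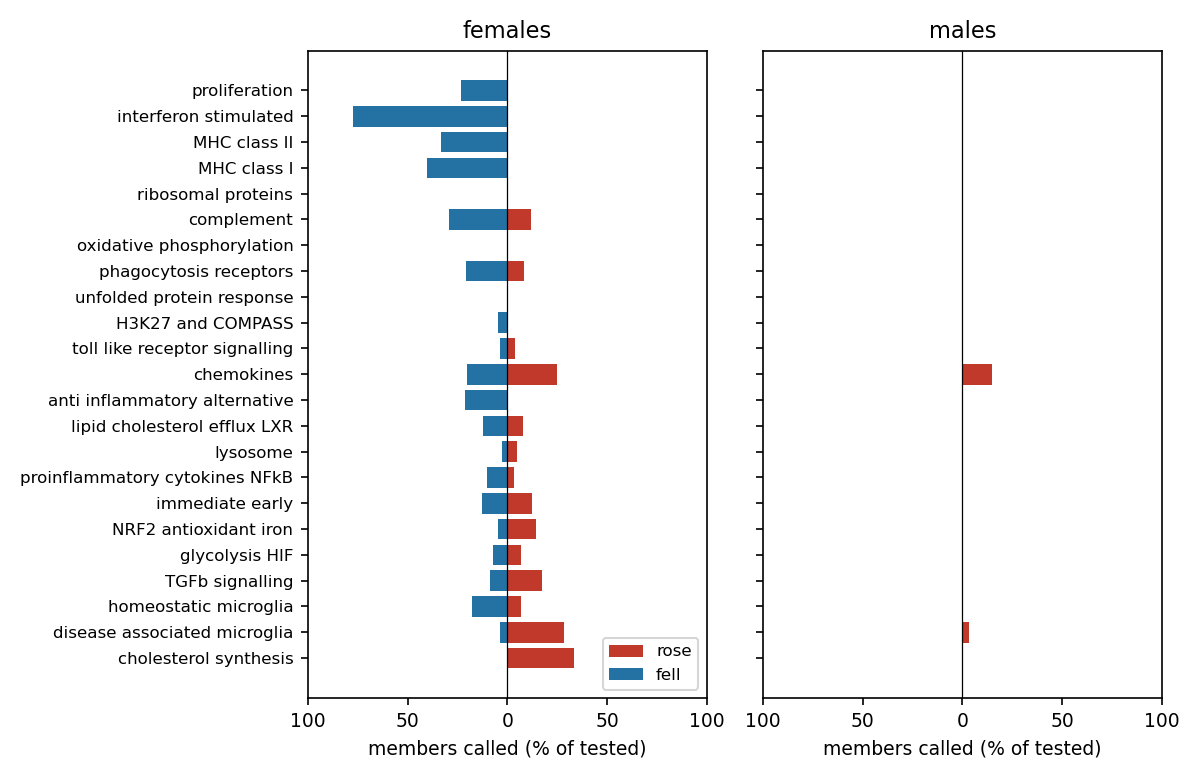
Members of each gene list that rose (red, to the right) or fell (blue, to the left) in cKO, as a percentage of the members tested, in females and in males. In females 31 of 40 interferon-stimulated genes fell and 7 of 21 cholesterol synthesis genes rose, and in males bars appear for chemokines (3 of 20 rose) and disease-associated microglia (1 of 28 rose).

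Females and males were also compared within each genotype. In wildtype, 6 genes passed, all on the sex chromosomes: *Xist* and *Tsix* were higher in females and the Y-linked *Kdm5d*, *Ddx3y*, *Eif2s3y* and *Uty* lower. The count was 2 with title number, partly shared by females and males of a genotype, as a fixed term, 2 in a fit of the groups compared alone and 22 by DESeq2, and *Uty* did not pass without female wildtype replicate 1 or 2 (adjusted p = 0.056 and 0.059). The pooled female wildtype levels of *Xist* and *Tsix* stood 722-fold and 54.7-fold above a floor of 3 counts over the 6 male wildtype libraries. If both mates of a read pair were counted separately, that floor would be higher and these folds smaller. Reads of *Xist* and *Tsix*, an overlapping antisense pair, cannot be told apart. The genes next in line, *Perp*, *Tchh* and *Krt71* on the higher side (adjusted p = 0.36, 0.36 and 0.58) and *Igf2bp3* on the lower (adjusted p = 1.0), did not pass, and at an unadjusted p under 0.05 there were 520 genes. *Kdm6a* was 0.69 higher in female wildtype on the log2 scale (SE 0.25), which did not pass across all genes (adjusted p = 1.0) and gave p = 0.0325 in the exact permutation test for this gene (n = 6 each). The Y-linked and X escape lists were called in the directions of the sexes with an estimated correlation too (adjusted p = 2.3e-06 and 4.2e-05). The proliferation list was higher in female wildtype (median 1.07, and 0.34 and 1.67 without female wildtype replicate 5 or male wildtype replicate 3; camera adjusted p = 9.3e-18; adjusted p = 0.64 with an estimated correlation).

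In cKO, 328 genes differed by sex, 308 of them autosomal. *Pld4* (-1.61, SE 0.13, adjusted p = 2.3e-08), *Themis2* (-1.24), *Gpr35* (-2.83) and *Tspan7* (-1.02) were lower in females beside the Y-linked *Kdm5d* (-7.19; the female cKO libraries other than replicate 1 held 0 counts), and *Il20rb* (2.51), *Tgfb2* (2.43), *Mmp2* (1.06) and *Lyz1* (2.05) higher beside *Xist* (7.06; the male cKO libraries other than replicate 3 held 0 counts). Of the interferon list 7 of 40 were lower in female cKO (30 adjusted over the list alone; median -0.78; camera adjusted p = 2.5e-26; adjusted p = 0.14 with an estimated correlation). Fits of replicates 1 to 3 and 4 to 6 alone gave 129 and 75 genes, the fit without the 4 doubted libraries 549, the fit with title number as a fixed term 549, and DESeq2 516. Without male cKO replicate 1 the count was 208.

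Genes on the X chromosome were called in females at a rate close to that of autosomal genes (51 of 624 and 1218 of 15654; odds ratio 1.05, Fisher's exact p = 0.703). Within 5 Mb of *Kdm6a*, 6 of 33 tested neighbours were called in females (18.2%, against 7.74% of all genes). *Cask* (1.01), *Maoa* (1.01), *Maob* (1.15), *Chst7* (0.70) and *Elk1* (0.48) rose in female cKO and *Cfp* (-2.37), the gene for the complement factor properdin, fell, though *Cfp* did not pass without the 4 doubted libraries (-1.53, adjusted p = 0.21). Calls of *Chst7* and *Elk1* were lost in 5 and 11 of the 12 fits with 1 female library left out.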

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

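Tests chosen only after the result was seen were the comparison of *Kdm6a* loss between the sexes, the splits of title numbers, GC content and transcript length taken separately, the removal of the 4 doubted libraries, the thinning of counts, the infiltrating-cell covariate and the fits that use replicates 1 to 3 against 4 to 6.

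In 12 of 118 groups of 6 values, 1 library stood apart from the other 5 by more than Dixon's 95% limit. For independent normal values chance gives about 1 in 20, or 5.9. Where a gene of the other sex was at 0 in the other 5 libraries, any count passes that limit, so 12 and 5.9 cannot be compared directly. Male wildtype replicate 2 had a total of 36.8 M counts, against 29.2 M to 31.1 M in the rest of its group. Female cKO replicate 1 had a *Tmem119* level of 8.19 in log2(CPM+1), against 7.58 to 7.69. Marker scores stood apart for fibroblasts in female cKO replicate 4 (4.87), neutrophils in male wildtype replicate 1 (1.38), monocyte-derived cells in male cKO replicate 1 (2.12), erythroid cells in female wildtype replicate 3 (0.56) and Schwann cells in female cKO replicate 2 (3.55). Genes of the other sex gave the remaining ones, in log2(CPM+1). Female wildtype replicate 3 had *Uty* at 0.28 and *Eif2s3y* at 0.68, female cKO replicate 1 had *Kdm5d* at 0.16 and *Eif2s3y* at 0.081, and male cKO replicate 3 had *Xist* at 0.54. In female wildtype replicate 3 *Ddx3y* reached 8.75% of the male wildtype mean, and in male cKO replicate 3 *Xist* reached 3.85% of the female cKO mean.

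Genotype effects differed between the sexes by the test of the difference itself for 68 genes. Among named genes the difference in log2 change, females minus males, was positive for *Acpp* (1.79), *Adora2a* (2.01), *Cspg4* (1.56), *Igf2bp3* (2.26), *Il20rb* (2.29), *Lyz1* (2.14), *Madcam1* (3.16), *Mmp2* (1.11) and *Tgfb2* (2.70). It was negative for *Alox5ap* (-2.69), *C4b* (-2.19), *Ebi3* (-1.54), *Fcgr4* (-3.28, and -2.55 and -2.51 without female wildtype replicate 5 or male cKO replicate 1), *Gpr35* (-3.03), *Grap* (-1.36), *Itgal* (-2.22), *Liph* (-1.02), *Pld4* (-1.65), *Themis2* (-1.18), *Tmem154* (-1.72) and *Tspan7* (-0.99). Calls for *Acpp* and *Cspg4* were lost in 12 and 2 of the 24 fits with 1 library left out.

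The larger genotype effect in females was weighed against 4 explanations. A few deviating libraries, a difference in depth and RNA of neurons and glia are argued against as whole causes: the count in females was 18.1 times that in males without the 4 doubted libraries, 48.6 times with every library thinned to the smallest total and 25.4 times with the neuron, astrocyte and oligodendrocyte covariate. These are ratios of called genes. At edgeR's unadjusted p under 0.05 the counts lay closer, with 3174 and 803 genes in all libraries. They were 2269 and 1069 in replicates 1 to 3 and 2904 and 485 in replicates 4 to 6. Such counts include genes that pass by chance, a share of 0.05 of those tested where nothing changed. The male counts were below that share in all libraries and in replicates 4 to 6, and above it in replicates 1 to 3. The ratio of these counts therefore does not measure how close the effects are. A weaker loss of *Kdm6a* in males stays open by the test made, although the point estimate runs the other way (difference in log2 change 0.52, SE 0.36), because the floxed exons are not given and residual reads measure loss only in part. Biological differences between the sexes, the dose of *Kdm6a* and the presence of *Uty* among them, were not tested. Differences between title numbers and in infiltrating cells were not weighed for this pattern either. Over methods that used all 24 libraries, male calls ran from 2 to 204.

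The lower interferon-stimulated genes in female cKO were weighed against 3 explanations. RNA of neurons and glia is argued against, since the median log2 change was -1.02 with that covariate and -1.05 without it. Influence of 1 library is argued against as the whole cause. With each female library left out in turn, 21 to 33 members were called lower and the median ran from -1.22 to -0.91. The lowest count, 21 without female wildtype replicate 5 (median -0.91), only just met the bound of at least 21 set for the test. A part may therefore rest on that library. Fewer infiltrating cells, or fewer monocyte-derived cells in the female cKO samples, may account for part of it, since the median moved to -0.67 and 4 members were called with the infiltrating-cell covariate. The covariate averages immune gene scores, of which the monocyte-derived one was lower in female cKO, so it cannot tell fewer cells from lower expression in microglia. With surrogate variables, of unknown source, the median was -0.66 and 22 members were called.

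The count of genes changed in females was weighed against other structure among the libraries. Each group was split evenly between replicates 1 to 3 and 4 to 6, so a constant difference between these sets could not by itself give a genotype effect. The test asked instead whether the effect was found in each set alone. In the same direction within both, 273 genes were called, where independent lists would share 9.57. Female wildtype replicates 3 and 4, of different sets, share a title number, so the sets may not be independent. Differences between title numbers, each of which belongs to 1 genotype, are argued against as the whole cause. With the counts of the female libraries of each number summed, genotype called 203 genes, and the other 34 splits of the 7 numbers called at most 2. At an unadjusted p under 0.05 genotype gave 1914 genes and other splits up to 3167, so the numbers differ in other ways too. For the rest of the 1279 genes this test has fewer units and leaves such differences open. GC content is argued against as the whole cause at a Spearman rho of 0.0531 in size with the female log2 change across genes, which are not independent replicates, while transcript length stays open at 0.226.

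Chance was examined with 100 splits of the libraries per comparison, the real one included, each library taken as a unit whatever its title number. If libraries are independent units, chance is argued against for the 1279 genes in females (1 split as large, highest other 962) and the 31 in males (1, highest other 1). The same holds for the 1082 averaged over the sexes (1, highest other 38) and the 328 differing by sex in cKO (1, highest other 4). Libraries that share a title number may not be independent. Differences between title numbers stay open for the 31 male genes. Limma with title number as a random effect called 2, and with counts summed over each of the 5 numbers genotype called 1 gene and another split 24, where 10 splits are too few for a share under 0.05. No split of the title numbers was made for the 1082 genes, so such differences stay open there too. For the 68 genes whose effect differs between the sexes 3 splits were as large (highest other 4560), a share under 0.05. These splits redrew genotype within each sex and so removed the genotype effect itself. They therefore cannot exclude chance for a difference in effect between the sexes, nor the structure described below. For the 6 genes differing by sex in wildtype 6 were as large (highest other 3099), so the splits do not exclude chance for that number. For the genes themselves the libraries do: *Xist* had 122 to 1035 counts in each female wildtype library and 0 in every male one, and *Kdm5d* 0 to 4 and 90 to 157, and *Tsix*, *Ddx3y*, *Eif2s3y* and *Uty* did not overlap either. In these 2 comparisons some splits called many times the real count, which points to a structure of the samples. Those with the most genes put mostly libraries of replicates 1 to 3, or of 4 to 6, together, but other such splits called 0 or 1 gene, so these sets do not account for it by themselves. Within the sets the effect differed between the sexes for 15 and 4 genes, and 4 and 4 genes differed by sex in wildtype.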

How the results depend on the processing

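Alternatives with replicates 1 to 3 against 4 to 6, without the 4 doubted libraries, with halved or thinned counts and with the infiltrating-cell covariate were chosen after seeing the data.

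For genes changed by genotype in females, 23 of 27 alternatives kept the count of 1279 within 1.5 times (980 to 1619 with 1 library left out, 869 without the 4 doubted libraries, 1572 by DESeq2). The others were 803 with title number as a random effect, 1965 with surrogate variables, and 458 and 658 in replicates 1 to 3 and 4 to 6 alone. The infiltrating-cell covariate was not among these 27, so they do not show how the count holds with it. The 31 genes in males became 89 by DESeq2, 2 with title number as a random effect, 90 with quality weights, 54 with the neuron, astrocyte and oligodendrocyte covariate, 204 with surrogate variables, 48 without the 4 doubted libraries and 0 and 0 by edgeR in replicates 1 to 3 and 4 to 6 alone (1069 and 485 at an unadjusted p under 0.05), and 15 to 30 with 1 library left out. The 68 genes whose effect differs between the sexes became 150 by DESeq2, 104 with title number as a random effect, 166 with surrogate variables, 111 with a term for the replicate sets, and 15 and 4 in each set alone, and 43 to 87 with 1 library left out. The 1082 genes changed by genotype averaged over the sexes became 330 with title number as a random effect, 2149 with surrogate variables, and 463 and 546 in the replicate sets (923 to 1278 with 1 library left out). The 6 genes differing by sex in wildtype became 22 by DESeq2, 2 in a fit of the groups compared alone and 2 with title number as a fixed term (5 to 6 with 1 library left out). The 328 genes differing by sex in cKO became 516 by DESeq2, 515 in a fit of the groups compared alone, 609 with quality weights, 1173 with surrogate variables, 549 with title number as a fixed term, 549 without the 4 doubted libraries, 516 with a term for the replicate sets, and 129 and 75 in the sets alone, and 208 to 335 with 1 library left out. *Kdm6a* kept its direction throughout, from -0.99 to -0.74 in females and -1.56 to -1.23 in males with 1 library left out, and lost its female call without the 4 doubted libraries (-0.81, adjusted p = 0.092; up to 0.37 over its alternatives). With an estimated correlation camera called 0 lists in females, males, the difference and the average (12, 11, 12 and 11 with the preset one; fry called 12, 0, 0 and 5), and 2 in each comparison of the sexes. With the neuron, astrocyte and oligodendrocyte covariate, 8 lists in place of 15 differed by sex in cKO. Marker scores past the threshold in females went from 2 to 0 with a median over members. The correlation between the sexes rose from 0.416 to 0.589 over genes of at least 10 CPM. Among called named genes the 1 direction that reversed was *Phf19* in females, from -2.12 to 0.37 with the infiltrating-cell covariate. Of the other named genes called in females, 53 kept their call with that covariate and 52 lost it. Smaller sets of libraries have fewer samples to test; otherwise the cause was not tested. For the genotype comparisons no paired analysis was possible because the replicate numbers follow accession order and each title number belongs to 1 genotype. At these depths, changes of 1.5-fold in libraries simulated as independent were recovered for 30% of genes in the female and 26% in the male comparison. These genes were drawn from those with a mean of at least 1 CPM.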

Other observations

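The infiltrating-cell covariate, the fit without the 4 doubted libraries and the comparison of replicates 1 to 3 with 4 to 6 were chosen after seeing the data.

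Single members of further gene lists changed in female cKO, while the lists were not called. Among genes of lipid efflux and the LXR pathway 2 of 25 rose and 3 fell (2 and 4 adjusted over the list alone), with the apolipoproteins *Apoc4* (-2.54) and *Apoc2* (-1.73) lower. In glycolysis and hypoxia response 2 of 29 rose and 2 fell (3 and 2 adjusted over the list alone): the growth factor *Vegfa* (1.21) and the glucose transporter *Slc2a1* (0.68) rose while the hexokinase *Hk3* (-1.48) fell. In female wildtype replicate 5 *Hk3* stood at 455 CPM, against 65.7 to 115 in the rest of its group, and without that library its change was -0.72 (adjusted p = 0.038). Immediate early genes split 3 and 3 of 24 (3 and 4 adjusted over the list alone), with the transcription factors *Egr1* (0.74) and *Egr2* (1.12) higher, and 1 fell without female wildtype replicate 3 or female cKO replicate 1, 2 or 3. Of alternative activation genes 3 of 14 fell (4 adjusted over the list alone), the receptor subunit *Il4ra* (-1.14) among them, and 1 fell without female wildtype replicate 5. Camera called none of these lists (adjusted p = 0.64, 0.25, 0.55 and 0.27).

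Markers of other cells also moved apart within lists. Of 8 dendritic cell markers 2 rose and 2 fell (3 and 2 adjusted over the list alone), with the actin bundler *Fscn1* at 1.86 and the chemokine receptor *Xcr1* at -3.67. Without female wildtype replicate 5, 3 rose and 1 fell. Of 15 endothelial markers *Flt1* rose (1.25) and *Kdr* (-1.45) fell, and 2 fell without female wildtype replicate 2. Of 12 monocyte-derived cell markers 4 fell, *Thbs1* (-1.07) among them, while *Fn1* (1.18) rose.

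Replicates 1 to 3 and 4 to 6 gave the female effect separately. Of 455 and 658 genes called among 16258 tested in both, 273 were shared, all in the same direction (111 higher and 162 lower, where independent lists would share 2.97 and 6.60), and the log2 changes correlated with r = 0.613 across genes, which are not independent replicates. In males the same correlation was 0.220. In each sex a title number has libraries in both sets, so the sets may not be independent. Between the sets 3793 genes were higher and 3678 lower in replicates 4 to 6, and the difference had a Spearman rho of 0.661 with GC content and -0.397 with transcript length over 16304 genes.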
